A study of Homo sapiens with 6 samples.

How the data were processed

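RNA from HCCLM3 cells carrying a hairpin against SPC25 (3 samples) or a control hairpin (3 samples) was labelled with Cy3 and hybridised to 1-colour Agilent arrays of 62976 spots, 1 array per sample. Groups and replicate numbers came from the sample titles, because the genotype label reads SPC25 knockdown on all 6 samples, and the hairpin sequence is not given in the sources used here. The scanner headers place the arrays on 2 slides, each with both groups. The deposited intensity values are processed spot signals made with Agilent Feature Extraction 10.7.1.1, per the file headers and the submitters' processing notes: 1-colour protocol, background subtraction, spatial and multiplicative detrending, and surrogates for dim spots, with no scaling between arrays. Probe positions are on hg19 (GRCh37), per the file headers. The deposited value table holds log2 values of the same arrays, as the authors made them; its scaling method is not stated, but all 6 columns hold the same sorted values over 58341 probes, as quantile normalization leaves them, and each column correlated above 0.998 with the log2 scanner signal of its array.

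The 2075 control spots and 117 to 200 outlier spots per array were left out, no spot was saturated, and each array's 75th percentile of log2 processed signal over the 60901 non-control spots was subtracted. Spots of 1 probe were averaged. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which kept 32732 of 58201 probes. Of these 58201, 31100 were named through a RefSeq accession, 3369 by a current symbol and 497 through a synonym, while 23235 kept the file's name. Each gene was represented by its kept probe with the highest mean over the 6 arrays, giving 25138 genes. The number of arrays, 3 per group, limits the precision of every value.

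Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided, R 4.3.3, with the package data.table at version 1.17.8) and Benjamini-Hochberg adjustment over all genes, with an adjusted p under 0.05 as the threshold; every gene p-value given is from this model unless another test is named. The 51 gene lists (1182 distinct genes tested) were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives, and chromosomes as gene sets in the same way, leaving out Y. The groups, designs, gene lists and the rule for named genes were fixed before the data were examined; lists of integrins, focal adhesion and PI3K-AKT were written knowing that the study's paper discusses ITGB4, FAK, PI3K and AKT. That rule names the NDC80 complex and ITGB4, the 12 protein-coding genes with the largest significant, non-overlapping change in each direction that were well above background on all 3 arrays of the higher group, the 4 members with the smallest p in each list described, and all members of a list with 5 or fewer genes tested. Alternatives were quantile and median scaling, the percentile over detected probes, normexp with an offset of 50, other probe filters and summaries, outlier spots kept, the value table, a trend and robust prior, array weights, replicate and slide blocks, a threshold of 0.01, and each array left out in turn. Either slide alone and shSPC25 replicates 2 and 3 averaged were added after the data were seen.

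The procedure was tested on simulated data. With the spread of these arrays over 25133 genes, it recovered 2.99% of genes changed 1.5-fold, 23.9% of those changed 2-fold and 69.7% of those changed 4-fold, and 4 of 68 calls were unchanged genes. Of 51 lists 0 were called with no shift, and 28 of 29 lists of at least 20 genes were called with a log2 shift of 0.3. The simulated genes varied independently of each other, whereas the estimated correlation within a list of these data reached 0.966. The simulation therefore does not show how often camera calls lists of correlated genes by mistake. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Values of some single members of the lists are not reported here.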

Results

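The series measured mRNA in HCCLM3, a human hepatocellular carcinoma cell line with a high capacity to metastasise, after lentiviral delivery of a short hairpin RNA against SPC25 (shSPC25) or a control hairpin (shNC). SPC25 encodes a subunit of the NDC80 complex, the part of the outer kinetochore that binds spindle microtubules. Each group held 3 arrays, and each array was hybridised with Cy3-labelled cRNA from 1 sample. The groups were taken from the sample titles, because the genotype label read SPC25 knockdown on all 6 samples. Between 58.6% and 65.6% of the 60901 non-control spots lay well above background on each array, and the 75th percentile of the spot signal ran from 241.6 on shSPC25 replicate 1 to 502.4 on shNC replicate 3. The arrays lay on 2 slides, slide 1 with shSPC25 replicate 1 and shNC replicates 1 and 2, and slide 2 with shSPC25 replicates 2 and 3 and shNC replicate 3. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these arrays, which may be technical.

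The first question was whether the hairpin lowered its target. SPC25 mRNA was lower on all 3 shSPC25 arrays than on all 3 shNC arrays. Its log2 signal relative to the array's 75th percentile was 1.58, 2.01 and 2.04 on shSPC25 replicates 1, 2 and 3, against 3.18, 3.08 and 2.94 on shNC replicates 1, 2 and 3. The means were 1.88 ± 0.26 (SD, n = 3) and 3.07 ± 0.12 (SD, n = 3), so that SPC25 fell by 1.19 on the log2 scale (SE 0.17), to 43.8% of the shNC level (limma, adjusted p = 0.0237). The difference was -1.23 with the slide as a block (adjusted p = 0.0164), -1.55 within slide 1 and -0.91 within slide 2. One probe, A_23_P51085, measured SPC25; the files place it on chromosome 2 from 169727956 to 169728015 (hg19), and its exon was not looked up. The SPC25 call was lost without shSPC25 replicate 2 (adjusted p = 0.0959) or 3 (0.104), without shNC replicate 1 (0.0654), 2 (0.114) or 3 (0.0981), with all probes tested (0.109) and with shSPC25 replicates 2 and 3 averaged (0.0876). The difference stayed between -1.27 and -1.04 with any 1 array left out.

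The 3 partners of SPC25 in the NDC80 complex did not pass the test. NUF2 differed by -0.05 (SE 0.12, adjusted p = 0.855), NDC80 by 0.21 (SE 0.12, adjusted p = 0.353) and SPC24 by -0.28 (SE 0.16, adjusted p = 0.361). ITGB4, the integrin β4 subunit of hemidesmosomes, was among the genes fixed in advance because it is known to feature in the study's paper. ITGB4 fell to 46.7% of the shNC level (SE 0.18 on the log2 scale, adjusted p = 0.0333), with a log2 difference of -1.16 with the slide as a block (adjusted p = 0.0207), -1.21 within slide 1 and -1.1 within slide 2. Its level was 1.58, 1.83 and 1.80 on the shSPC25 arrays and 2.51, 3.07 and 2.92 on the shNC arrays.

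**Figure D1:**
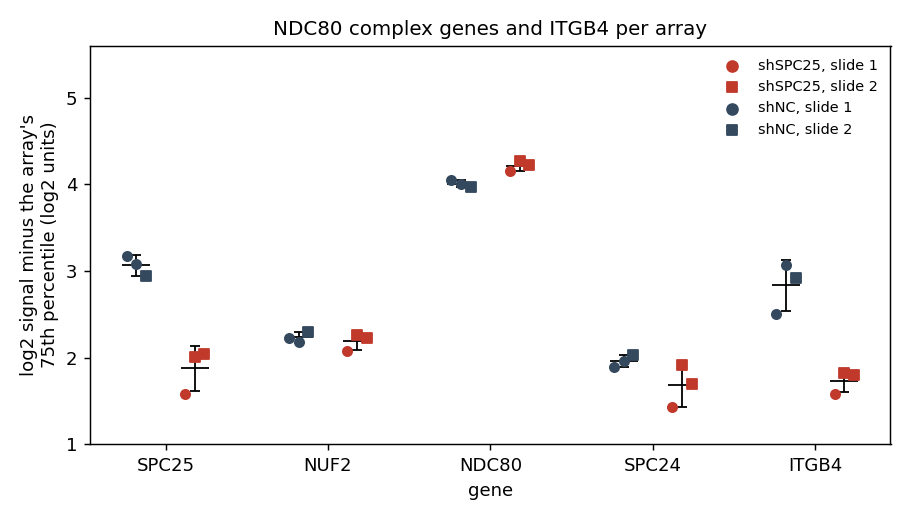
Log2 signal relative to the array's 75th percentile (vertical axis, log2 units) of the 4 NDC80 complex genes and ITGB4 (horizontal axis) on each array; red points are shSPC25, dark points shNC, circles slide 1 and squares slide 2, with black bars for the mean and SD of 3 arrays. All shSPC25 points lie below all shNC points for SPC25 and ITGB4, while NDC80 and NUF2 differed by 0.21 and -0.05.

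Across the transcriptome, 916 of 25138 genes differed between shSPC25 and shNC cells (limma, adjusted p under 0.05), 402 higher and 514 lower in shSPC25 cells, and 546 of them differed at least 2-fold (221 higher, 325 lower). Among protein-coding genes, 231 were higher and 296 lower of 14255 tested. All 916 changed genes had non-overlapping groups, which passing the test on the same values largely brings about. Of all tested genes 30.2% did, against 10% for exchangeable arrays. These arrays share slides, and shSPC25 replicates 2 and 3 are unusually alike, so that reference is only rough. All 916 were also called with the slide as a block, a fit that called 3392 genes (2118 higher, 1274 lower) and 1048 at least 2-fold. The share of changed genes that were higher was 43.9%, 62.4% with the slide as a block and 27% (190 higher, 513 lower) with each array scaled to its median. The count of 916 was not stable to the choice of arrays: it was 961 without shSPC25 replicate 1, 377 without shNC replicate 1, 49 without shNC replicate 2, and 0 without shSPC25 replicate 2, shSPC25 replicate 3 or shNC replicate 3 (4037, 3923 and 4880 genes at an unadjusted p under 0.05). It was also 0 when every probe was tested whatever its signal (5429 at an unadjusted p under 0.05) and when shSPC25 replicates 2 and 3, which were unusually alike, were averaged as 1 sample (3961).

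The genes with the largest fitted rise included the transcription factor RUNX3, at 0.57 ± 0.04 (SD, n = 3) in shSPC25 cells and -2.41 ± 0.31 (SD, n = 3) in shNC cells, a log2 difference of 2.98 (SE 0.18, adjusted p = 0.00593); its other probe gave 2.32. CCKBR, the receptor for gastrin and cholecystokinin, rose by 2.90 (SE 0.30), and ACSL5, an acyl-CoA synthetase for long-chain fatty acids, by 2.74 (SE 0.20). LAMA4, the laminin α4 chain, rose by 2.84 (SE 0.35) on its brightest probe and differed by 0.30 to 1.73 on its other 3 probes. For genes not well above background on every array of 1 group only a lower bound on the fold can be given: the brighter group's mean against the dim group's mean of, per array, the higher of the gene's own signal and the lowest signal well above background. PSG8, a pregnancy-specific glycoprotein, was at least 6.67-fold higher and SOST, the secreted Wnt antagonist sclerostin, at least 5.22-fold, both well above background on 1 of the 3 shNC arrays. For 6 further genes no shNC array lay well above background, so that their place among the largest rises rests on fitted values and is not established by their bounds. The chemokine CCL3 was at least 4.30-fold higher, the adhesion glycoprotein CEACAM6 at least 1.69-fold, IQCF1 at least 1.61-fold, PBDC1 at least 5.79-fold, PSG2 at least 1.91-fold and the sialyltransferase ST3GAL6 at least 1.80-fold. CCL3 stood at -1.41 on shSPC25 replicate 1 against -3.58 and -3.35 on replicates 2 and 3, so its bound, from the group mean, leans on replicate 1. PSG family members are near-identical in sequence, so the signal of PSG2 and PSG8 may be shared.

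The genes with the largest fitted fall included LEMD1, which was well above background on every shNC array and on no shSPC25 array, at least 7.02-fold lower. The organic anion transporter SLCO2B1 was at least 2.06-fold lower on the same terms, CYP4X1 at least 1.94-fold, the Rag GTPase RRAGD at least 1.97-fold, the lipid-droplet dehydrogenase HSD17B13 at least 2.90-fold and the GABA transaminase ABAT at least 3.05-fold; their place among the largest falls is likewise not established by these bounds. Complement factor I, CFI, fell by 2.92 on the log2 scale (SE 0.27), while its other probe gave -1.77 and did not pass the test. The cholesterol efflux transporter ABCG1 fell by 2.89 (SE 0.51), the drug-metabolising cytochrome CYP3A5 by 2.73 (SE 0.36) and the ubiquitin ligase gene MYLIP by 2.55 (SE 0.30). LGSN was at least 8.86-fold lower and PRR15L at least 7.18-fold, each well above background on 2 of the 3 shSPC25 arrays. The second CYP3A5 probe gave -0.98 and did not pass the test.

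**Figure D2:**
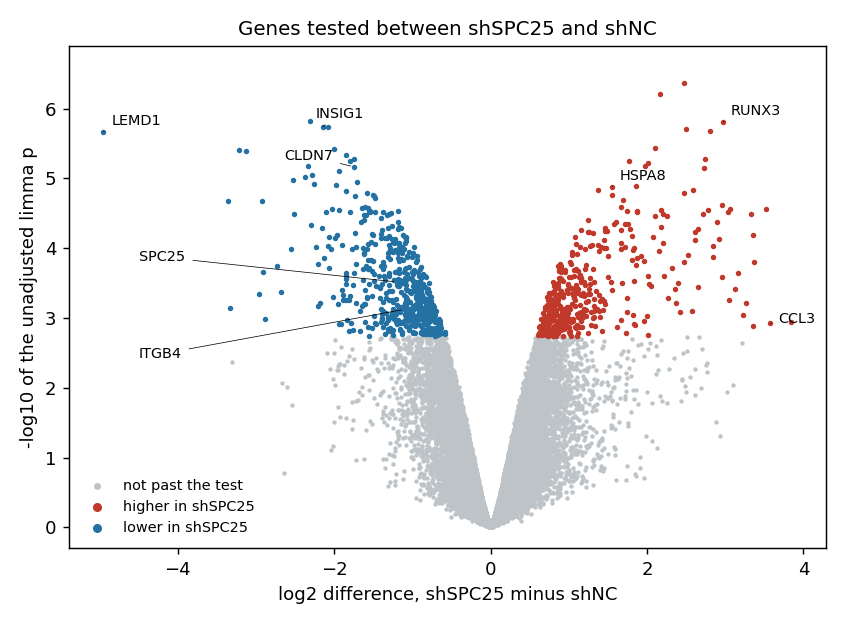
Log2 difference, shSPC25 minus shNC (horizontal axis), against the negative log10 of the unadjusted limma p (vertical axis) for each of 25138 genes; coloured points passed the adjusted test and grey points did not. The 402 genes higher (red) and 514 lower (blue) in shSPC25 cells include RUNX3 at 2.98 and LEMD1 at -4.95, a fitted value from a gene below background in shSPC25 cells.

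Of the 51 gene lists fixed in advance, 13 were called by camera with its preset correlation of 0.01, 5 higher and 8 lower in shSPC25 cells than the remaining genes. No list was called with an estimated correlation, where the smallest adjusted p was 0.482. That alternative is weak with so few arrays, which leave 4 residual degrees of freedom, or 3 with the slide as a block. The epithelial junction list had an estimated correlation of -0.0195, below the preset 0.01, yet its unadjusted camera p rose from 0.0119 to 0.0493. A call lost with an estimated correlation therefore does not show that a list is unchanged. The median log2 difference over all genes was 0.07, and it moved by -0.14 when arrays were scaled to their medians.

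Genes of lipid synthesis were lower in shSPC25 cells. Of 25 cholesterol synthesis genes, 3 fell, none rose and 22 did not pass the test, and 6 fell when adjusted over the list alone. INSIG1, which retains the sterol sensor complex in the endoplasmic reticulum, fell by 2.14 on the log2 scale (SE 0.13), while the lanosterol synthase gene LSS was at -0.92 (SE 0.24, adjusted p = 0.0908). The list had a median of -0.48 (camera, adjusted p = 1.03e-06, but adjusted p = 0.938 with an estimated correlation). It was -1.01 within slide 1 and -0.17 within slide 2, with an adjusted p of 2.19e-08 with the slide as a block, and -0.25 without shSPC25 replicate 1 (adjusted p = 0.00164). Of 22 fatty acid synthesis and storage genes, 6 fell, none rose and 16 did not pass the test, and 8 fell and 1 rose when adjusted over the list alone. FASN, the fatty acid synthase, fell by 1.60 (SE 0.24), SREBF1, the transcription factor that drives lipogenic genes, by 1.22 (SE 0.15), the desaturase FADS1 by 0.95 (SE 0.17) and the acyl-CoA synthetase ACSL3 by 0.80 (SE 0.12). The second SREBF1 probe gave 0.09. This list had a median of -0.28 (camera, adjusted p = 0.000307, but adjusted p = 0.938 with an estimated correlation). It was -0.59 within slide 1 and -0.18 within slide 2, with an adjusted p of 6.86e-05 with the slide as a block.

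Cytosolic heat shock genes were higher in shSPC25 cells. All 18 had a positive difference, 3 rose over all genes tested and 17 when adjusted over the list alone. The constitutive chaperone HSPA8 rose by 1.55 (SE 0.13), its co-chaperone DNAJA1 by 0.89 (SE 0.12) and BAG3, which links HSP70 to autophagy, by 0.88 (SE 0.12), while the inducible HSPA1B was at 1.23 (SE 0.31, adjusted p = 0.0818). The list median was 0.63 (camera, adjusted p = 1.59e-07, but adjusted p = 0.482 with an estimated correlation). It was 0.50 within slide 1 and 0.60 within slide 2, with an adjusted p of 3.15e-05 with the slide as a block.

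Genes of ribosome production and protein turnover had small positive differences. Spike-in controls, scaled in the same way, differed between shSPC25 and shNC arrays by -0.04 to 0.63. The medians of these lists lie within that range, and no comparison with random lists of similar signal was made for them. Among 38 MYC target and ribosome biogenesis genes 1 rose, NOP16 by 0.69 (SE 0.13), and 13 rose when adjusted over the list alone. The median was 0.41 (camera, adjusted p = 2.67e-05, but adjusted p = 0.938 with an estimated correlation). It was 0.33 within slide 1, 0.48 within slide 2, and the adjusted p was 0.000181 with the slide as a block. PPAN and BYSL, both factors of ribosome assembly, were at 0.74 (SE 0.15) and 0.69 (SE 0.14) without passing the test. None of the 34 proteasome and ubiquitin genes passed, also when adjusted over the list alone, and 33 had a positive difference; PSMC3 was at 0.52 (SE 0.13). Their median was 0.26 (camera, adjusted p = 0.0038, but adjusted p = 0.938 with an estimated correlation). It was 0.12 within slide 1, 0.35 within slide 2, with an adjusted p of 0.0356 with the slide as a block. None of the 59 ribosomal protein genes passed either way. Their median was 0.23 (camera, adjusted p = 0.00204, but adjusted p = 0.938 with an estimated correlation), turning to -0.08 with quantile normalization and to -0.11 in the deposited value table. It was 0.21 within slide 1, 0.09 within slide 2, and the adjusted p was 0.103 with the slide as a block. The ribosomal protein list was not called without shSPC25 replicate 2 (median 0.19, adjusted p = 0.0791) or shNC replicate 2 (0.13, 0.227). Without shNC replicate 2 the proteasome list was not called either (0.18, 0.114), and with normexp background neither the proteasome list (0.19, 0.138) nor the ribosomal protein list (0.17, 0.265) was. Either slide alone leaves 1 array in 1 group, shSPC25 on slide 1 and shNC on slide 2, so the medians within slides are given as sizes only.

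Interferon-stimulated genes were higher in shSPC25 cells mainly on 1 array. None of 43 passed the test, also when adjusted over the list alone, although 42 had a positive difference and the median was 0.88 (camera, adjusted p = 0.000482, but adjusted p = 0.938 with an estimated correlation). Relative to the shNC mean, the list averaged 2.64 on shSPC25 replicate 1, 0.28 and 0.31 on shSPC25 replicates 2 and 3, and 0.52, -0.23 and -0.29 on shNC replicates 1, 2 and 3. The same array stood high in the lists of NF-κB and inflammatory targets (0.78, against 0.07 and 0.09 on the other shSPC25 arrays) and of MHC and antigen presentation (0.78, against 0.24 and 0.14). The antiviral factor TRIM22 was at 2.34, -1.47 and -1.53 on the shSPC25 arrays and at -2.38, -3.33 and -3.60 on the shNC arrays (difference 2.88, SE 1.05, adjusted p = 0.177). IFI27 was at 1.86 (SE 0.53, adjusted p = 0.107) and SAMD9L at 1.76 (SE 0.65, adjusted p = 0.181). The median was 2.30 within slide 1 and 0.47 within slide 2, and 8 of the genes rose with the slide as a block (list adjusted p = 3.11e-07). Without shSPC25 replicate 1 the median was 0.25 and the list was not called (camera, adjusted p = 0.235). Slide 2, where the median was 0.47, lacks that array too but holds 1 shNC array, so no call there is interpreted. Without shSPC25 replicate 2 the median was 1.34.

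Targets of the integrated stress response and ATF4 were lower, with 3 of 35 genes falling and none rising, also when adjusted over the list alone. These were 3 enzymes of serine and cysteine synthesis, PHGDH by 2.10 (SE 0.21), CTH by 1.35 (SE 0.15) and CBS by 1.06 (SE 0.17), while PPP1R15A, a phosphatase subunit that ends the response, was at 0.55 (SE 0.18). The list median was -0.25 (camera, adjusted p = 0.00145, but adjusted p = 0.938 with an estimated correlation). It was -0.40 within slide 1, -0.06 within slide 2, with an adjusted p of 0.00846 with the slide as a block. The list stood 0.54 above the shNC mean on shNC replicate 1, and without that array its median was -0.02 and it was not called (adjusted p = 0.472).

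Epithelial junction genes moved both ways. Of 24 tested, 4 fell, 2 rose and 18 did not pass, and 9 fell and 3 rose when adjusted over the list alone. The tight junction gene CLDN7 fell by 1.74 (SE 0.13), the membrane protease gene ST14 by 0.93 (SE 0.16), the desmosomal gene DSP by 0.86 (SE 0.13) and EPCAM by 1.67 (SE 0.28), whereas KRT7, a keratin of simple epithelia, rose by 0.98 (SE 0.16) and LSR, a receptor of tricellular junctions named after its value was seen, by 0.93 (SE 0.17). The list median was -0.17 (camera, adjusted p = 0.0465, but adjusted p = 0.938 with an estimated correlation). It stood at -0.25 within slide 1, -0.10 within slide 2, with an adjusted p of 0.0237 with the slide as a block. The list was not called without shSPC25 replicate 1 (median -0.13, adjusted p = 0.239) or 2 (-0.15, 0.0791), nor without shNC replicate 1 (-0.21, 0.056) or 3 (-0.20, 0.246). It was also lost with median scaling (-0.31, 0.0869), quantile normalization (-0.17, 0.0769), the deposited value table (-0.18, 0.0709), a filter on all 6 arrays (-0.09, 0.0794) or the replicate block (-0.17, 0.0879). Its median was 0.02 with all probes tested.

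The other 4 lists called lower had small medians, no gene past the test over all genes or over the list alone, and an adjusted p of 0.938 with an estimated correlation. The G1/S and DNA replication genes (54 tested) had a median of -0.15 (camera, adjusted p = 0.00469), -0.25 within slide 1 and -0.06 within slide 2; POLD3, a subunit of DNA polymerase delta, was at -0.47 (SE 0.12). The DNA repair genes (36 tested) had a median of -0.13 (adjusted p = 0.004), -0.22 within slide 1 and -0.12 within slide 2; RAD51C was at -0.54 (SE 0.13). The oxidative phosphorylation genes (52 tested) had a median of -0.11 (adjusted p = 0.0102), -0.18 within slide 1 and -0.05 within slide 2, and the fatty acid oxidation genes (21 tested) of -0.20 (adjusted p = 0.0102), -0.37 within slide 1 and -0.11 within slide 2. With the slide as a block the adjusted p of these lists was 0.000293, 0.000597, 0.000745 and 0.00136 in that order, and without shSPC25 replicate 1 none was called (0.239, 0.0602, 0.239 and 0.346), with medians of -0.06, -0.12, -0.08 and -0.20. The oxidative phosphorylation list was also lost without shNC replicate 1 (median -0.10, adjusted p = 0.0836) or 3 (-0.11, 0.0719), and the fatty acid oxidation list without shNC replicate 3 (-0.21, 0.078), although these medians were about as large as over all arrays.

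**Figure D3:**
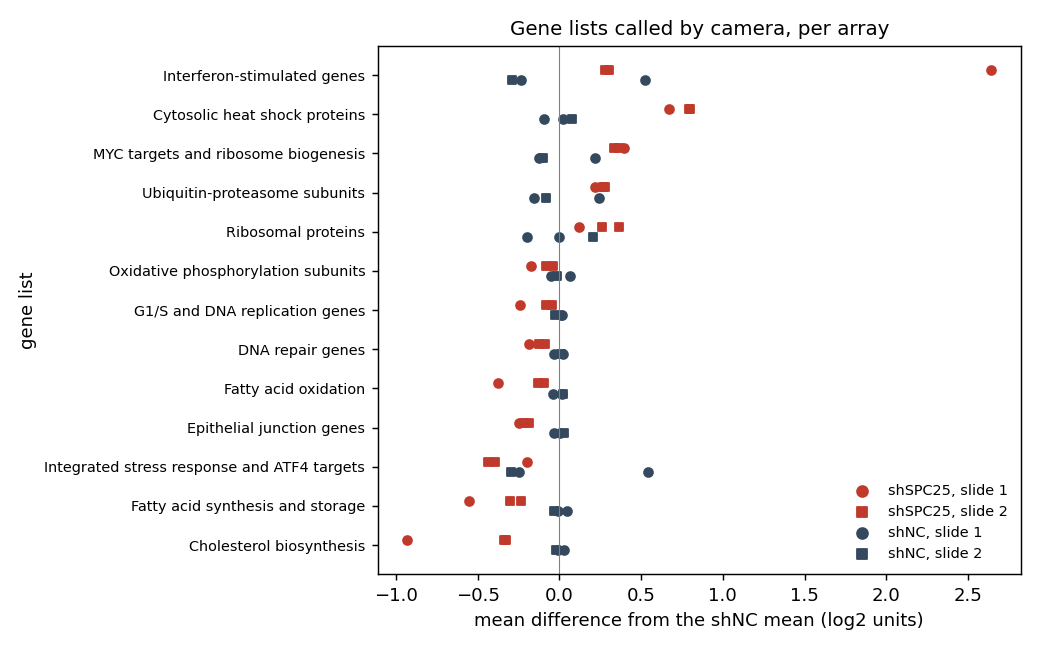
Mean over list members of the log2 signal minus the gene's shNC mean (horizontal axis, log2 units) for the 13 gene lists called by camera (vertical axis), 1 point per array; red points are shSPC25, dark points shNC, circles slide 1 and squares slide 2. Interferon-stimulated genes stand at 2.64 on shSPC25 replicate 1 and at 0.28 and 0.31 on the other shSPC25 arrays; the ribosomal protein median was 0.23 here and -0.08 with quantile normalization.

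Mitotic lists were not called by camera or fry. Of 32 outer kinetochore and CENP genes none passed the test (median -0.05, adjusted p = 0.287), nor did any of 17 spindle checkpoint genes (median 0.03, adjusted p = 0.741). Of 54 G2/M genes, the chromokinesin gene KIF4A rose by 0.85 (SE 0.16; adjusted p = 0.0454) over all genes and none passed when adjusted over the list alone; the list median was 0.01 while its test pointed lower (adjusted p = 0.463). Among 33 p53 targets, the cell cycle inhibitor gene CDKN1A rose by 0.76 (SE 0.14), while MDM2 was at 0.74 (SE 0.17) and BBC3, which encodes PUMA, at -0.68 (SE 0.14) without passing. This list was not called (adjusted p = 0.572), and 5 rose and 2 fell when adjusted over the list alone. Of 32 apoptosis genes none passed (adjusted p = 0.678).

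Lists of adhesion and of the FAK, PI3K and AKT route, which were included because the study's paper is known to discuss them, were not called. Of 18 integrin genes, ITGB4 fell and no other passed (median 0.27, adjusted p = 0.746), while 4 were higher and 2 lower past the test when adjusted over the list alone. ITGA6, its partner subunit, was at 0.69 (SE 0.15, adjusted p = 0.0579) and its second probe at 0.76 (SE 0.15), which passed when adjusted over all probes (adjusted p = 0.0454). None of 35 focal adhesion genes passed (median 0.00, adjusted p = 0.97), and of 24 PI3K-AKT-mTOR genes PIK3CD was at least 2.37-fold lower (well above background on 2 of 3 shSPC25 arrays), with 2 genes falling when adjusted over the list alone and a list median of -0.01 (adjusted p = 0.31). The second PIK3CD probe gave 0.48. The laminin chain genes moved apart: LAMA1 rose by 1.30 (SE 0.15), LAMA4 rose as given above, and LAMA3, a chain of the laminin that integrin α6β4 binds, fell by 1.71 (SE 0.14), although its second probe gave 0.06. The matrix proteoglycan gene LUM fell by 2.26 (SE 0.19), the matrix metalloproteinase gene MMP7 by 1.61 (SE 0.29), and the inhibitor gene TIMP3 rose by 1.16 (SE 0.20).

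Several signalling lists held changed genes without being called by camera. The MAPK and TGF-β lists below were called higher by fry (adjusted p = 0.0332 and 0.03), which does not compare a list with the other genes. Of 25 MAPK feedback and immediate early genes 4 rose and none fell (adjusted p = 0.08), among them the cyclin gene CCND1 by 1.82 (SE 0.22), the ERK phosphatase gene DUSP6 by 1.01 (SE 0.14) and FOSL1 by 0.99 (SE 0.17), while the ephrin receptor gene EPHA2 was 2.30-fold higher (SE 0.14 on the log2 scale). Of 21 TGF-β and BMP targets 3 rose and none fell (adjusted p = 0.306), ID2 by 1.87 (SE 0.16), SMAD6 by 0.98 (SE 0.15) and ID1 by 0.87 (SE 0.14). Adjusted over each list alone, 7 rose in both lists and 1 TGF-β target fell. Of 17 Wnt targets 2 rose and 2 fell (3 and 4 when adjusted over the list alone; list adjusted p = 0.859), with APCDD1 rising by 1.84 (SE 0.22) beside CCND1, and with NKD2 at -1.26 (SE 0.22) and the glutamine synthetase gene GLUL falling to 49.9% of shNC. The Notch target HES5 rose by 2.19 (SE 0.21) as the only gene past the test among 17 of that pathway, also when adjusted over the list alone (list adjusted p = 0.746).

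Hepatocyte lists moved both ways and were not called. Among 17 hepatic transcription factors, ONECUT2 rose by 1.67 (SE 0.16) and ONECUT1, well above background on 2 of 3 shNC arrays, was at least 1.73-fold higher, while CEBPA fell by 1.14 (SE 0.19; list adjusted p = 0.936), with 3 rising and 3 falling when adjusted over the list alone. Among 19 hepatocyte enzymes and transporters, CYP7A1, the rate-limiting enzyme of bile acid synthesis, was well above background on no shNC array and at least 1.99-fold higher in shSPC25 cells, and CYP3A5 fell (list adjusted p = 0.572; 2 higher and 3 lower when adjusted over the list alone). Among 23 secreted hepatocyte proteins, APOC3 was at least 1.09-fold lower, although its difference was 0.02 with normexp background correction, and SERPINA3 rose by 0.89 (SE 0.16; list adjusted p = 0.581). Adjusted over the list alone, 2 of these 23 rose and 7 fell. Marker lists of fibroblasts, endothelium, leukocytes, erythroid cells and neural or muscle cells were not called by camera (adjusted p = 0.678, 0.899, 0.581, 0.369 and 0.572), although fry called the erythroid list higher (0.0332). In the leukocyte list CD3E, well above background on 2 of 3 shNC arrays, was at least 4.79-fold higher and CSF1R fell by 1.18 (SE 0.15). The remaining lists were not called by camera, with adjusted p-values from 0.08 for MHC and antigen presentation, which was called with the slide as a block (adjusted p = 0.0294, but 0.872 with an estimated correlation), to 0.97 for collagens and interstitial matrix.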

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

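Either slide alone, the averaged replicates and the slide block for chromosomes were chosen after the data were seen. SPC25 was lower under every alternative run. It was not past the test with no filter (-1.19), on slide 1 only (-1.551) or slide 2 only (-0.9149), with shSPC25 replicates 2 and 3 averaged (-1.265), or without any 1 array other than shSPC25 replicate 1; leaving out 1 array gave -1.272 to -1.041. The 916 changed genes became 1542 with a trend and robust prior, 5358 with array weights, 3392 with the slide as a block, 27 at an adjusted p under 0.01, and 0 by limma with no filter, on either slide alone or with the averaged replicates (5429, 4837, 8972 and 3961 at an unadjusted p under 0.05), and lay between 0 and 961 with 1 array left out. The 546 genes changed at least 2-fold became 298 with normexp background, 1205 with array weights, 1048 with the slide as a block, and 0 with no filter, on either slide alone or with the averaged replicates, and lay between 0 and 655 with 1 array left out. Fewer samples or more tests account by construction for part of the loss on 1 slide, with averaged replicates and with no filter; the cause was not tested for the others. Of 13 lists called, 0 were called by camera with an estimated correlation (2 at an unadjusted p under 0.05), 2 were called by fry, which called 5 in all, and 12 were also called with the slide as a block. Either slide alone leaves 1 array in 1 group, so no call made or lost there is interpreted. The list medians within slides given above are sizes only. Among results past their test over all arrays or under an alternative with more than 1 slide, those that reversed were ribosomal proteins and APOC3. Ribosomal proteins were at -0.0757 with quantile normalization and -0.112 in the value table, and APOC3 at 0.01936 with normexp. On slide 1 only, with 1 shSPC25 array, the medians of replication-dependent histones (-0.119) and NRF2 targets (-0.145) also turned negative. The cause was not tested. The epithelial junction median was 0.0167 with no filter, although its test still pointed lower. Of 13 named genes with a sign change under some alternative, only APOC3 had passed the test, and of 30 lists whose median changed sign, 2 had been called. Of 4963 values of 217 named genes, 3952 kept direction and side of the threshold, 674 fell below it and 308 rose above it. Of 1173 values of 51 lists, 1032 kept both, 33 fell below and 32 rose above. The trend and robust prior and the array weights do not enter the list test, so the 51 list calls under each could not change. Genes near background are limited by their signal, as the bounds given for them show.

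Whether the replicate numbers pair the samples cannot be told, because pairing is mixed with the slide. Deviations of same-numbered samples correlated at 0.513 and 0.474 for replicates 1 and 3, which share a slide. They correlated at -0.1 for replicate 2, which does not. Over all shNC arrays, shSPC25 replicate 2 correlated best with shNC replicate 3 (0.471), the only shNC array on its slide. Because shSPC25 replicates 2 and 3 are unusually alike, the values 0.471 and 0.474 are not separate evidence. With the replicate block 1129 genes changed (708 at least 2-fold), SPC25 was at -1.19 (limma, adjusted p = 0.0432) and 13 lists were called, 12 of them shared; the epithelial junction list was lost (0.0879).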

Other observations

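The name families, the closeness of replicates and the tests of a single array or slide were chosen after the results were seen, and the splits were not. The predictions for the tests against random lists were written beforehand. The lists and the array used in those tests, however, follow patterns already seen in the results. Among name families with at least 5 genes tested, 2 held more changed genes than the rest by Fisher's exact test, adjusted over families. Of 5 pregnancy-specific glycoprotein genes 4 rose (adjusted p = 0.000164), with PSG5 at least 2.90-fold and PSG6 at least 1.84-fold higher beside PSG2 and PSG8. Of 8 clustered protocadherin β genes, which encode neural-type adhesion proteins, 4 fell (adjusted p = 0.00589), with PCDHB16 at -1.55 (SE 0.15), PCDHB14 at -1.12 (SE 0.16), PCDHB15 at -1.09 (SE 0.16) and PCDHB11 at -0.85 (SE 0.14). Members of both families are similar in sequence, so their probes can share signal.

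Without shSPC25 replicate 1, 3 lists not called over all arrays were called by camera. NRF2 targets had a median of 0.52 (adjusted p = 7.83e-06, against 0.114 over all arrays), hypoxia targets of -0.68 (0.00163, against 0.114) and replication-dependent histones of 0.44 (0.0233, against 0.79). With an estimated correlation the adjusted p without that array was 0.633 for the NRF2 list and 0.991 for the others, so none was called. The shSPC25 arrays left, replicates 2 and 3, are unusually alike and lie on slide 2, while shNC replicates 1 and 2 lie on slide 1. These calls therefore cannot be fully told apart from a slide difference. Relative to the shNC mean, the NRF2 list stood at -0.19, 0.50 and 0.48 on shSPC25 replicates 1, 2 and 3, and the hypoxia list at 0.41, -0.71 and -0.75, against 0.67, -0.28 and -0.39 on the shNC arrays.

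The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 916 changed genes and the highest other 798, a count reached by 1 split, the real one. For genes changed at least 2-fold the values were 546 and 595, reached by 2 splits. In both, the highest other was the split by slide, and the real comparison gave 3392 and 1048 with the slide as a block; slides also separated on the second principal component (34% of the variance). The other 8 splits gave 0 genes by limma. For lists called the real split gave 13 and the highest other 17, reached by 6 splits, and the other splits called 8 to 17. No chromosome was called in any of the 10 splits (smallest adjusted p of the real one 0.426, with 1 chromosome at an unadjusted p under 0.05), nor with an estimated correlation (0.991) or the slide as a block (0.691).

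Interferon-stimulated genes were higher in shSPC25 mainly on replicate 1, where all 43 lay above every shNC array, against 9 on all 3 shSPC25 arrays. A difference between slides as the whole cause is argued against by medians above 0 within both slides, each with 1 array in 1 group. With the slide as a block the list was called (camera, adjusted p = 3.11e-07). It was not called with the slide block and an estimated correlation (0.872), so that call does not decide it. Level-dependent scaling of that dim array is argued against by random lists of the same mean level, of which 0.01% (the smallest share 10000 lists can give) reached its median of 2.40 over the other shSPC25 arrays. Whether the call rests on replicate 1 alone cannot be told: without it the median was 0.25 and the list was not called (camera, adjusted p = 0.235). That fit sets replicates 2 and 3, both on slide 2, against shNC arrays of both slides. Slide 2 alone, which lacks replicate 1 too, gave a median of 0.466, but with its single shNC array no call there is interpreted. Whether the hairpin or the handling of that sample raised these genes was not tested and stays open.

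Lipid synthesis genes were lower in shSPC25, with 14 of 25 cholesterol and 11 of 22 fatty acid genes below every shNC array on all 3 shSPC25 arrays. Above every shNC array on all 3 were 0 cholesterol and 3 fatty acid genes. Over all tested genes, 30.2% had non-overlapping groups in either direction. Replicate 1 as the only low array is argued against by list means per array. The cholesterol mean was -0.93 on it, -0.34 and -0.33 on shSPC25 replicates 2 and 3, and 0.028, -0.008 and -0.02 on the shNC arrays. The fatty acid mean was -0.551, -0.236 and -0.302 on the shSPC25 arrays and -0.009, 0.044 and -0.035 on the shNC arrays. Without replicate 1 both lists were called (camera, larger adjusted p 0.00755, but 0.633 for both with an estimated correlation). The cholesterol median went from -0.48 to -0.25. In that fit the shSPC25 arrays, replicates 2 and 3, are unusually alike and lie on slide 2. Because shNC replicates 1 and 2 lie on slide 1, it cannot fully separate group from slide. A difference between slides is argued against by medians of -0.78 and -0.17 over both lists within slides 1 and 2, each with 1 array in 1 group. With the slide as a block both lists were called (camera, larger adjusted p 6.86e-05). Neither was called with the slide block and an estimated correlation (0.872 for both), so those calls do not decide it. Level-dependent scaling is argued against by random lists of the same level, of which 0.01% reached the joint median of -0.38. The hairpin and culture conditions stay open as explanations, since neither was tested and both lists lose their call with an estimated correlation (adjusted p = 0.938).

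Replicates 2 and 3 of shSPC25 were closer than any other pair, with an SD of log2 differences of 0.23. Sharing a slide is argued against as the whole cause, since the closest other pair on 1 slide had 0.426. That pair, shNC replicates 1 and 2, was the only other pair sharing both slide and group, so the argument rests on 1 pair. Their difference over probes with 10 spots was 4.23 times that between spots, against 9.26 to 26.6 for other pairs, so they differed by more than spot noise. One RNA sample hybridised to both arrays cannot be told apart from separate cultures, because no known repeat hybridisation sets the bound. Averaged as 1 sample, they left 0 changed genes by limma (3961 at an unadjusted p under 0.05).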
